A study of Mus musculus with 5 samples.

How the data were processed

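Total RNA of 5 mouse samples was profiled on 1-colour probe-set arrays, with 1 array per sample. Per the labels, every sample held dendritic cell progenitors from bone marrow that carry FLT3 and CD11b, and the samples were numbered 1 to 5. The labels refer to an earlier publication for RNA preparation, labelling and hybridization, and give no animal, pool, treatment or date. All samples therefore formed 1 group, and no comparison between conditions was possible.

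The deposited values were intensity values on a linear scale, 1 per probe set and array, for 12488 probe sets. The software that made them is not given in the sources used here. The lowest value was 0.1, and no pair of columns was identical. The mean of the deposited intensity values after leaving out 2% at each end was 1001 in sample 1 and 200.1 in each of the other samples; the scaling step is not given in the sources used here. Column medians were 392, 72.7, 76.9, 66.5 and 81.2 for samples 1 to 5.

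The 66 control probe sets were left out, and each array was multiplied by 1 factor to a common median of 103.4. Values under the 25th percentile of all scaled values, 30.0, were raised to it before log2 was taken; signals quoted per gene are scaled values before this step. Genes were named through the platform annotation supplied with the series, and a mouse RefSeq gene table (assembly GRCm38.p6) was used only to look for newer symbols, which gave 0 changes. Of 12422 probe sets, 10833 had 1 gene symbol, 396 had several and were not named, and 1193 were not listed. The 8251 named genes were each represented by the probe set with the highest mean log2 signal. In the fixed lists, 118 genes had several probe sets, and in 44 of these the probe sets fell on different sides of the limit described next.

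No detection call came with the values, so each array's median served as the limit. A gene counted as above the limit when it exceeded the median on all 5 arrays. This limit ranks a probe set within its array and does not show that a transcript is present or absent.

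Before the data were examined, 25 gene lists were fixed with 454 genes, of which 401 were measured, together with the tests, the alternatives and the rule for genes named in the text. The list of ribosomal proteins was taken by symbol and leaves out kinases and other genes whose symbols only begin alike, which is narrower than its first wording. The rule allowed the gate genes Flt3 and Itgam, the first 4 measured genes of each list, list genes with an outlying sample by Dixon's test at 95%, and the 15 named genes with the lowest p for variance. Genes outside it are named only where a count was small, and were chosen after their values were seen.

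The share of each list above the limit was compared with all other named genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 25 lists. Spread and shift used probe sets with a mean above the median, 5814 in all, which represented 4556 named genes, and lists with at least 5 such genes. Spread was the median over a list's genes of the SD of log2 signal across samples. Shift was the median over a list's genes of a sample's log2 signal minus the gene's mean over all 5 samples. Both were set against 10000 random lists of the same size matched on decile of mean signal in two-sided permutation tests, adjusted over 20 lists for spread and over 100 pairs of list and sample for shift. Genes are not independent, so these p-values describe the arrays at hand. Matching by decile does not separate levels within the highest decile. Variable probe sets were sought with limma by setting each variance against a robust scaled F distribution with a trend on mean signal. An adjusted p of 0.05 was the threshold throughout.

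The procedures were tested on simulated data in which 5 arrays had the real mean levels. Each simulated gene varied independently of the others, and no simulated array deviated by signal level. The rates of false calls given next therefore do not cover real lists whose genes move together or share a high level. Of 221 simulated sets with no change, 7 gave any call for spread and 4 gave any call for shift. The first of these sets gave 2 false calls among 20 lists for spread, which prompted the other 220; across all sets 5.16% of spread tests had an unadjusted p under 0.05. A shift of 1 log2 unit in the 20 mitosis genes was called in 21 of 21 sets and a shift of 0.5 in 6 of 21. An SD of the 20 DNA replication genes raised by a factor of 2 was called in 21 of 21 sets and a factor of 1.5 in 10 of 21. Among 5814 probe sets, limma's variance test called 22 of 200 with an SD raised by a factor of 4 and 154 of 200 with a factor of 8, with 1 and 3 false calls beside them and 0 where nothing was changed. Fisher's exact test called 0 of 25 lists with random genes above the limit and a list with all genes above it.

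Alternatives were the values as deposited, quantile normalization, every probe set on its own, limits at the 40th and 75th percentile, a limit passed in at least 3 samples, other filters and floors, unmatched random lists, a non-robust fit, an added offset, and leaving out each sample in turn. Scaling to a common 2% trimmed mean was added after the data were seen. The top 1% level and the 5 lists whose spread was followed across alternatives were also chosen after the data were seen. The number of arrays limits the precision. Nothing in the labels says that the samples came from separate animals, so SDs measure only the spread between these samples, which may be technical in part. The list tests set genes against other genes, and limma sets probe sets against each other. Their p-values therefore do not measure variation between animals. The Xist and Eif2s3y signals of each sample are given with the closing observations. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.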

Results

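Gene expression was measured in 5 samples of mouse bone marrow cells that carry FLT3, a receptor tyrosine kinase of early blood progenitors, and CD11b, the myeloid integrin chain encoded by Itgam. The labels name these cells dendritic cell progenitors and give 1 group of 5 samples, so the data answer which gene programmes had signal in these cells and how far the samples differed. Signals are scaled array intensities, given as mean ± SD over n = 5 samples, and the common array median was 103.4.

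Both genes of the sort had signal above the median on all 5 arrays, Flt3 at 745 ± 463 and Itgam at 477 ± 215. Kit, the stem cell factor receptor, lay above it on all 5 arrays at 184 ± 35.1, and the progenitor antigen gene Cd34 on 3 of 5 at 127 ± 51.5. Of the gate and progenitor list, 7 of 15 genes were above the limit, which did not pass the test against other named genes (Fisher's exact test, adjusted p = 1). Across all named genes, 3674 of 8251 (44.5%) were above the limit.

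Neutrophil granule genes were above the limit more often than other genes, with 15 of 16 genes (Fisher's exact test, adjusted p = 0.000616). They included Mpo, myeloperoxidase of primary granules, at 6085 ± 2069.8, and Elane, neutrophil elastase, at 5823 ± 3524. S100a8, a calcium-binding protein of granulocytes and monocytes, reached 49978 ± 27812, and Ltf, lactoferrin of secondary granules, 4573 ± 3264. The remaining gene, Mmp9, was above the limit on 3 arrays; like other genes said here to lie outside the naming rule, it was chosen after values were seen. Of the monocyte and macrophage list, 13 of 20 genes were above the limit, which did not pass the test (exact adjusted p = 0.111). Among them were the lysozyme gene Lyz2 at 9082 ± 4126, the endotoxin co-receptor gene Cd14 at 559 ± 151, Cd68 at 1107 ± 304 and Adgre1, which encodes F4/80, at 465 ± 60.9.

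Cell division genes were likewise above the limit more often than other genes. The mitosis list had 19 of 21 genes there (Fisher's exact test, adjusted p = 0.000465) and the DNA replication list 18 of 22 (adjusted p = 0.00250). Mki67, a marker of cycling cells, had a signal of 2199.8 ± 524, the mitotic kinase gene Cdk1 1106 ± 366 and the topoisomerase gene Top2a 969 ± 224. Pcna, the sliding clamp of replication, had 3419.6 ± 976, the helicase subunit gene Mcm5 1684 ± 614 and the ribonucleotide reductase gene Rrm2 995 ± 416.

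Genes of mature and plasmacytoid dendritic cells were above the limit on every array less often than other genes. The mature list had 2 of 16 genes there (Fisher's exact test, adjusted p = 0.0249), namely Fscn1, an actin-bundling protein, at 339.6 ± 73.1, and Clec4a2, which lies outside the naming rule. Itgax, which encodes CD11c, had 96.2 ± 52.4, the costimulatory gene Cd86 124 ± 72.4 and the homing receptor gene Ccr7 47.1 ± 31.3. The plasmacytoid list had 0 of 7 genes above the limit (exact adjusted p = 0.0377), with Irf7 at 61.0 ± 35.3 and Spib at 95.7 ± 104. Of the 7 genes, 5 were above it on some arrays and 2 on none. Pacsin1 was above it on 4 arrays at 167 ± 83.5. Cox6a2, outside the naming rule, was above it on 2 arrays, with 1274 in sample 2. The mature list lost its call without sample 1 (exact adjusted p = 0.0739) and the plasmacytoid list without sample 4 (exact adjusted p = 0.170). With 3 arrays sufficing, the share of the mature list was 50% against 12.5%, and its call was lost (exact adjusted p = 0.643). It was also lost with the limit at the 40th (0.169) and 75th percentile (0.368). The low share of the mature list thus depended on the limit and on requiring every array. The plasmacytoid list lost its call with 3 arrays sufficing (exact adjusted p = 0.0982) and at the 75th percentile (0.527).

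The MHC class I list was above the limit more often than other genes, with 10 of 12 genes (Fisher's exact test, adjusted p = 0.0222), among them B2m, the light chain of class I molecules, at 7108 ± 2883, and the peptide transporter gene Tap1 at 253 ± 66.0. The MHC class II list had 5 of 13 genes there (exact adjusted p = 0.816). Of these, the invariant chain gene Cd74 had 306 ± 93.6 and the protease gene Ctss 6343 ± 3925, while H2-DMa, Lgmn and Cst3 lie outside the naming rule. The class II chain genes H2-Ab1, at 31.3 ± 13.8, and H2-Aa, at 55.8 ± 48.7, were above the limit on 0 and 1 arrays.

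Regulators and receptors of myeloid cells had signal in part, and neither list passed the test. Of the dendritic cell transcription factors, 12 of 22 were above the limit (exact adjusted p = 0.447). They included Spi1, which encodes PU.1, at 910.5 ± 386, and Id2 at 3977 ± 1976, while Irf8 was above it on 4 arrays at 274 ± 126 and Relb on 2 at 112 ± 89.3. Of the myeloid growth factor receptors, 11 of 16 were above the limit (exact adjusted p = 0.111), among them Csf1r, the M-CSF receptor, at 498 ± 297, and the GM-CSF receptor genes Csf2ra at 521 ± 171 and Csf2rb at 464 ± 337.

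Markers of most other lineages were above the limit less often than other genes. The T and NK cell list had 1 of 18 genes there (Fisher's exact test, adjusted p = 0.00250) and the B cell list 1 of 17 (adjusted p = 0.00371), which were Cd28 and Ighm, both outside the naming rule. Cd3e, a T cell receptor component, had 23.7 ± 11.6, and Cd79a, a B cell receptor component, 91.6 ± 106. The stromal and endothelial list had 3 of 19 genes above the limit (exact adjusted p = 0.0249), namely fibronectin, Fn1, at 1403 ± 678, with Col1a2 and Pecam1 outside the rule. This call was lost without sample 2 (exact adjusted p = 0.0721) and without sample 3 (0.0643). Erythroid and megakaryocyte genes, 4 of 12 (exact adjusted p = 0.615), and mast cell, basophil and eosinophil genes, 4 of 15 (exact adjusted p = 0.237), did not pass the test. The first 3 of the latter, Cpa3 at 1238 ± 597, Prg2 at 302 ± 135 and Mcpt8 at 553 ± 109.8, encode granule proteins and were above the limit on all 5 arrays.

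Interferon response genes were above the limit less often than other genes, with 1 of 15 genes (Fisher's exact test, adjusted p = 0.0102). The gene was Ifi204, outside the naming rule, while Isg15 had 103 ± 32.8 and Mx1 52.3 ± 22.01. Inflammatory cytokines and chemokines, 5 of 19 (exact adjusted p = 0.205), did not pass the test, with Ccl3 at 424 ± 82.4 and Il1b at 23.2 ± 19.3. Immediate early genes, 11 of 18 (exact adjusted p = 0.205), included Fos at 1626 ± 859 and the phosphatase gene Dusp1 at 1188 ± 667.

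Housekeeping genes, 10 of 10 (Fisher's exact test, adjusted p = 0.00250), glycolysis genes, 11 of 13 (adjusted p = 0.0131), and heat shock genes, 11 of 14 (adjusted p = 0.0282), were above the limit more often than other genes. Examples were Ldha, lactate dehydrogenase, at 5109.9 ± 1542, Pkm, pyruvate kinase, at 5513 ± 2112, and the chaperone genes Hspa8 at 3900.2 ± 486 and Hspa5 at 4763 ± 713. The heat shock call was lost without sample 1 (exact adjusted p = 0.0538) and without sample 3 (0.0538). Cholesterol synthesis genes, 9 of 12 (exact adjusted p = 0.0699), ribosomal proteins, 22 of 35 (exact adjusted p = 0.0699), and sex-linked genes, 0 of 4 (exact adjusted p = 0.186), did not pass the test. Ribosomal proteins passed with the limit at the 75th percentile (exact adjusted p = 6.49e-05), with 3 arrays sufficing (0.0481) and without sample 5 (0.0499). Cholesterol synthesis genes passed with 3 arrays sufficing (exact adjusted p = 0.0481) and without sample 1 (0.0364), and immediate early genes at the 75th percentile (0.0207). In all, 7 lists were above the limit more often and 6 less often. The 6 became 1, the T and NK cell list, with the limit at the 75th percentile, and 2, with the interferon list, when 3 arrays above the median sufficed. The glycolysis list (exact adjusted p = 0.0996) and the heat shock list (0.229) also lost their calls there. With the limit at the 40th percentile the MHC class I (0.0650), heat shock (0.0854), mature dendritic cell (0.169) and stromal lists (0.0650) lost theirs and the gate and progenitor list gained 1 (exact adjusted p = 0.0210).

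**Figure D1:**
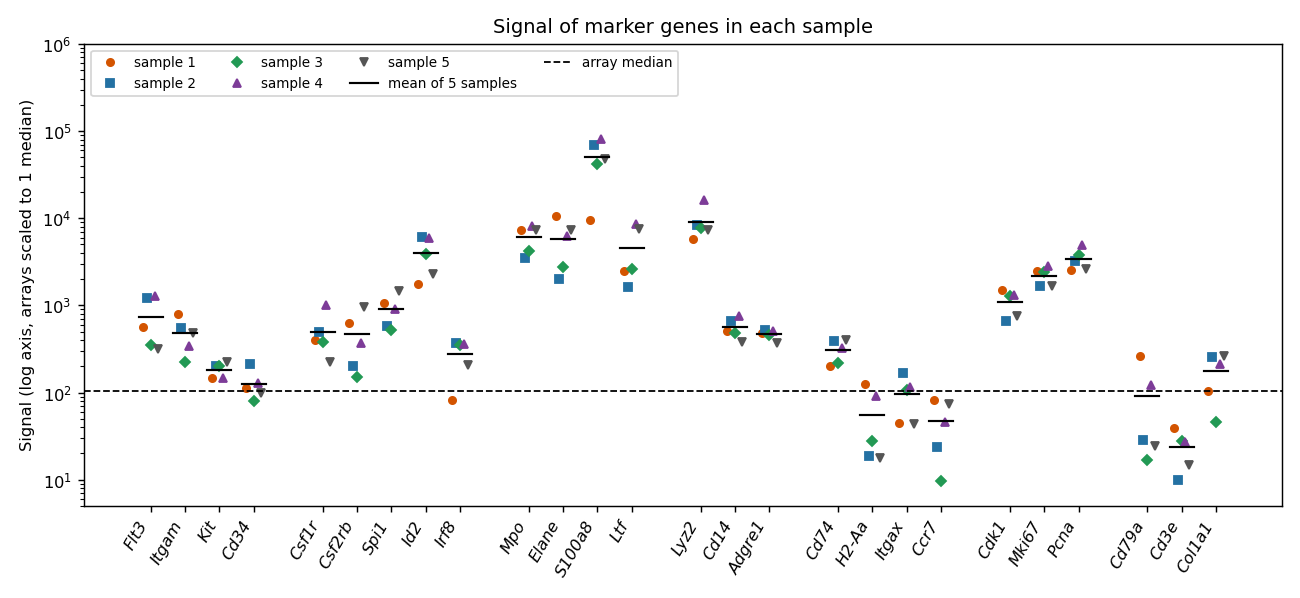
Scaled signal of marker genes in samples 1 to 5 on a log axis, with the mean of 5 samples as a bar and the array median of 103.4 dashed. Flt3, Itgam, the granule genes and the cell cycle genes lie above the dashed line in all 5 samples, and Cd3e and Ccr7 below it in all 5.

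The samples resembled each other to different degrees. Pearson's r of log2 signal across 5814 probe sets, which are not independent replicates, ran from 0.791 for samples 1 and 3 to 0.907 for samples 2 and 4. The median SD between samples was 0.47 on the log2 scale. Sample 1 differed at high signal: the 125 probe sets in the top 1% by the mean of the other samples lay a median of -0.64 log2 units from that mean in sample 1, with 107 of 125 lower. In sample 4 the same measure was 0.48, with 8 of 125 lower. The 3' over 5' signal ratio of the actin control was 1.08, 3.0029, 4.15, 5.20 and 2.55 in samples 1 to 5, that of the Gapdh control 0.896, 1.06, 4.52, 3.42 and 2.01, and that of the transferrin receptor control 3.14, 3.77, 16.7, 8.63 and 5.16. The last 2 were highest in sample 3.

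**Figure D2:**
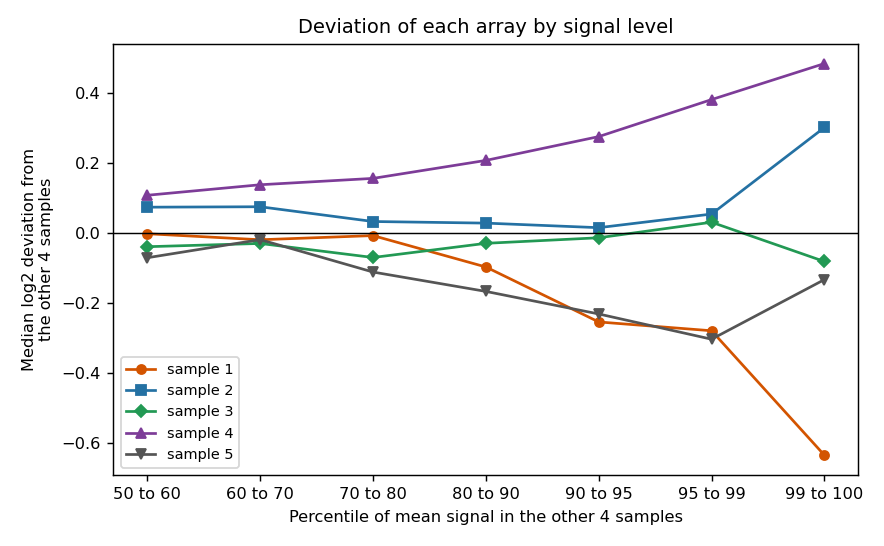
Median log2 deviation of each sample from the mean of the other 4 samples, for probe sets binned by percentile of that mean. Sample 1 falls to -0.64 and sample 4 rises to 0.48 in the top 1%.

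Neutrophil granule genes were the 1 list of 20 that differed more between samples than genes matched on decile of mean signal. Their median SD was 0.84 on the log2 scale against 0.45 in random lists (permutation test, adjusted p = 0.00400, unadjusted p = 0.0002, the smallest that 10000 lists can give). Matching by decile does not extend to the top 1% of probe sets, which lay at -0.64 in sample 1 and 0.48 in sample 4. Signals of S100a8 in samples 1 to 5 were 9540.2, 68953, 41773, 82007 and 47618, those of Elane 10647, 2027, 2760.0, 6325 and 7356 and those of Ltf 2449, 1609, 2604, 8611 and 7593. The call was lost without sample 1, the array with the lower top signals, where the median SD was 0.51 against 0.41 (permutation adjusted p = 0.294). It was also lost in the values as deposited (permutation adjusted p = 0.176). There sample 1 kept its higher trimmed mean of 1001, and the median SD of all probe sets was 1.12. That setting cannot separate the spread of the list from this offset. Over all alternatives the permutation adjusted p ran from 0.00300 to 0.294. Immediate early genes (permutation adjusted p = 0.106) and dendritic cell transcription factors (0.173) did not pass, but did without sample 3 (0.0380) and without sample 4 (0.0342).

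Several gene groups lay together above or below their 5-sample mean in single samples, in 16 of 100 pairs of list and sample. Shifts are given in log2 units relative to level-matched random lists. The deviations of a gene from its own 5-sample mean balance out over the samples. Calls of the same list in several samples are therefore not separate findings. DNA replication genes were lower in sample 2 by a shift of -0.46, with 18 of 20 genes below their mean (permutation adjusted p = 0.00800), the 1 shift past the threshold under every alternative. Glycolysis genes were lower in sample 2 (-0.51, 9 of 12 genes, permutation adjusted p = 0.0120) and higher in sample 1 (0.53, 9 of 12 genes, adjusted p = 0.0286) and sample 5 (0.44, 8 of 12 genes, adjusted p = 0.0233). Ldha signals in samples 1 to 5 were 6643, 2644, 4841, 5334 and 6088. Neutrophil granule genes were higher in sample 4 (0.53, 13 of 15 genes, permutation adjusted p = 0.00800) and sample 5 (0.41, 12 of 15 genes, adjusted p = 0.00800) and lower in sample 3 (-0.43, 11 of 15 genes, adjusted p = 0.01000). The top 1% of probe sets, to which matching by decile does not extend, lay at 0.48 in sample 4, and without sample 1 the neutrophil shift there was 0.30 (permutation adjusted p = 0.00373).

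Mitosis genes were lower in sample 2 (-0.32, 16 of 20 genes, permutation adjusted p = 0.0453) and higher in sample 3 (0.30, 18 of 20 genes, adjusted p = 0.0120). Cholesterol synthesis genes moved likewise, lower in sample 2 (-0.56, 11 of 11 genes, permutation adjusted p = 0.0114) and higher in sample 3 (0.50, 8 of 11 genes, adjusted p = 0.00800). Sqle, squalene epoxidase, had 572 in sample 2 and 1368 in sample 3. Ribosomal protein genes were higher in sample 2 (0.32, 23 of 26 genes, permutation adjusted p = 0.0246) and lower in sample 3 (-0.30, 18 of 26 genes, adjusted p = 0.0233). Immediate early genes were higher in sample 2 (0.45, 11 of 14 genes, permutation adjusted p = 0.0120), where Fos had 2622 and Dusp1 1818; the shift was 0.28 with no filter on signal and no longer called. MHC class I genes were lower in sample 3 (-0.42, 10 of 11 genes, permutation adjusted p = 0.049995). Inflammatory genes were higher in sample 5 (1.01, 3 of 5 genes, permutation adjusted p = 0.00800), a direction that turned with no filter on signal; without sample 1 the shift was 0.48.

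Of the 16 shifts, 4 passed whichever other sample was left out, namely DNA replication and glycolysis genes in sample 2 and neutrophil genes in samples 4 and 5. The others lost their calls without sample 1 (inflammatory, permutation adjusted p = 0.103), sample 2 (mitosis 0.157, cholesterol 0.259 with a shift of 0.27 and ribosomal 0.119 in sample 3, glycolysis 0.0963 in sample 1 and 0.24982 with a shift of 0.24 in sample 5), sample 3 (mitosis 0.153, immediate early 0.118, ribosomal 0.260 and cholesterol 0.138 in sample 2, glycolysis 0.0729 in sample 1), sample 4 (MHC class I 0.0706, neutrophil 0.212 with a shift of -0.25 and cholesterol 0.0709 in sample 3, mitosis 0.188 and ribosomal 0.0532 in sample 2) or sample 5 (neutrophil 0.0587 with a shift of -0.25 in sample 3). Quantile normalization ended 8 of the 16, among them the neutrophil shift in sample 4, which fell to 0.22 (permutation adjusted p = 0.122). The neutrophil shift in sample 3 shrank to -0.27 there and the ribosomal shift in sample 2 to 0.17. Counting every probe set shrank the neutrophil shift in sample 3 to -0.21, and ended that in sample 5 at 0.26 (permutation adjusted p = 0.104) and the glycolysis shift in sample 2 at -0.31 (0.156).

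**Figure D3:**
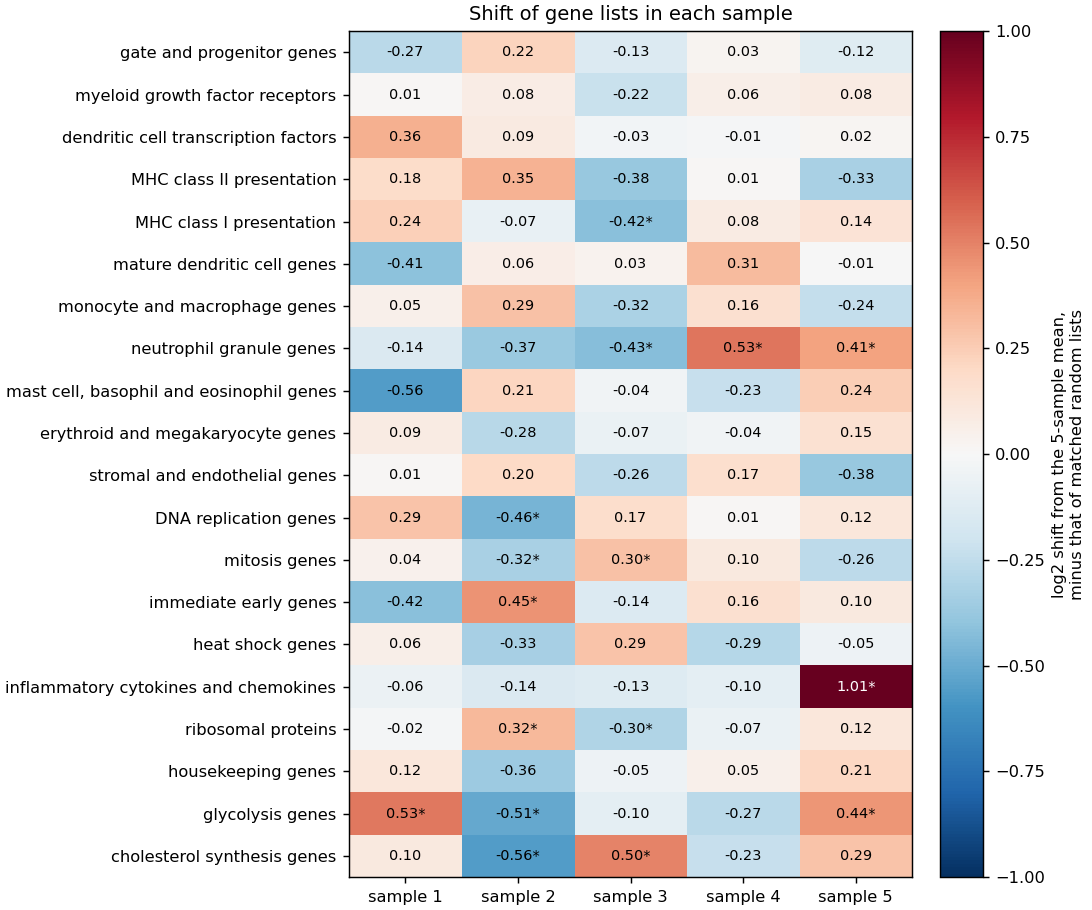
Shift of each gene list in each sample in log2 units, as the median deviation from the 5-sample mean minus that of level-matched random lists. Red is higher, blue lower, and asterisks mark the 16 pairs past the threshold.

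Single probe sets did not pass the test for variance. In simulated data this test called 22 of 200 probe sets whose SD was raised by a factor of 4. Differences of that size between samples could thus be missed. The F distribution was fitted to these same variances, so the test ranks probe sets against each other. It cannot show whether the samples differ as a whole. Counts at an unadjusted p under 0.05 therefore have little meaning by themselves. Limma called 0 of 5814 at the adjusted threshold with 290 at an unadjusted p under 0.05, and 0 with 294 in the non-robust fit. With a lower floor and no filter it called 10 of 12422. Adjusted over the list alone, 0 of 248 genes of the fixed lists passed. The named genes with the lowest p were Apoe, an apolipoprotein of macrophages, with signals of 1158, 1109, 83.4, 16.8 and 80.7 in samples 1 to 5, the transcription factor gene Klf13 with 558, 38.3, 418, 941 and 695, and the proteoglycan gene Vcan with 117, 596, 375, 959 and 18.7. Next came Scd1, a fatty acid desaturase, with 976, 44.7, 714, 181 and 352. All had a limma adjusted p of 0.925. The other genes among the 15 were Rbfox2, Rpl41, Sla, Polr1c, Ms4a6c, Rab7, Xist, Wnk1, Dpm2, H3c14 and Cpeb2.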

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

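Dixon's test compares the gap of the most extreme of the 5 samples with their whole range, and ratios above 0.71 are listed; chance alone gives about 5%, and 13 of 260 genes were listed. The test in this part was written before its result was seen, with its signal levels chosen after the data were seen.

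Low in sample 3 were the class I genes Tap1 (ratio 0.715, signal 143) and H2-D1 (0.762, 1494), the lysosomal reductase gene Ifi30 (0.818, 74.1), the chemokine receptor gene Cx3cr1 (0.826, 37.5), Il3ra (0.757, 147) and Polr1c (0.776, 21.9). Low in sample 2 were the ligase gene Lig1 (0.715, 241) and Klf13 (0.747, 38.3). In sample 4, Fscn1 (0.780, 215) and Pacsin1 (0.716, 34.1) were low and fibronectin, Fn1 (0.74979, 2603), high. In sample 5, Sox4 (0.826, 340.3) was high, as was the median shift of the inflammatory list (ratio 0.745, shift 0.88), 1 of 20 lists tested.

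Sample 1 stood apart in the ribosomal protein gene Rpl41 (ratio 0.962), with a signal of 1601 against 27881 to 31178 in the others. It also stood apart in 3 of 14 array measures, the deposited trimmed mean (ratio 0.99998), the deposited median (0.955) and the 25th percentile over the median (0.859).

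The top probe sets were lower and closer together in sample 1, with an SD of 0.68 log2 units against 0.74 to 1.01 in the other samples, and its highest deposited value was 128 times its median against 404 to 793 times. A signal ceiling in sample 1 may account for the pattern: in 40 genes with a bright and a dimmer probe set, the bright one deviated lower in sample 1 by a median of -0.98, in 31 genes. The same median was between -0.13 and 0.31 in the other samples. This comparison cannot tell a ceiling from other technical causes that act differently on the probe sets of a gene. The lower signals of sample 1 were not confined to the top 1%. Its median deviation was -0.25 from the 90th to the 95th percentile and -0.28 from the 95th to the 99th. Sample 5 had -0.23 and -0.30 there. Rpl41, at 1601 in sample 1, lay below the 10647 of Elane on the same array. A common ceiling would thus not account for its low signal. Sample 1 also had the lowest 3' over 5' ratio for each of the 3 controls, at 1.08, 0.896 and 3.14. A ceiling remains a hypothesis, a different share of granule-rich cells was not tested, and no biological explanation from the design was tested, because the labels give 1 group.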

How the results depend on the processing

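Scaling to a trimmed mean, chosen after seeing the data, kept every count of calls. Lists above the limit more often numbered 6 to 9 under the alternatives, not always the same lists; lists above it less often were 1 with the limit at the 75th percentile and 2 with at least 3 samples above it, and lists with higher spread 0 as deposited. Shift calls were 8 after quantile normalization, 10 with every probe set, 10 with the floor at the 10th percentile and no filter together and 9 with unmatched lists, against 16. Variable probe sets were 10 with that floor and no filter together, against 0. The median SD was 1.12 as deposited, 0.53 with no filter, 0.69 with both changes and 0.35 with an offset; the lowest r was 0.868 with no filter alone and 0.834 with both. Turned in direction were the share of gate and progenitor genes (37.5%) and of MHC class II genes (40%) with every probe set, neither called; the spread of erythroid genes against random lists (0.0185 as deposited, 0.0491 with no filter, 0.11 with both changes), of immediate early genes (-0.16 as deposited) and of ribosomal proteins (0.0042 with no filter); and the inflammatory shift in sample 5 (-0.11 with no filter, -0.10 with both changes). Leaving out each sample in turn gave 6 to 8 lists more and 5 to 6 less often above the limit, 0 to 2 with higher spread (0 without sample 1, 2 without samples 3 or 4), 7 to 21 shifts (7 without sample 2, 8 without sample 3), a median SD of 0.42 to 0.47 and a lowest r of 0.789 to 0.831. Lists with under 5 genes left gave no value, and without sample 1, where the common median comes from the other arrays, mean signals of 24 of 123 genes moved by over 1 SD. The cause of the other changes was not tested. No paired analysis was possible because the labels give 1 group. Signal over background limits what was seen of genes near the median.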

Other observations

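The gene lists and tests in this part were chosen after the data were seen, except the test of the neutrophil spread without sample 1. Genes of oxidative phosphorylation were above the limit more often than other genes, with 49 of 63 (Fisher's exact test, adjusted over 9 lists, p = 1.11e-06). So were genes of the phagocyte NADPH oxidase, which makes superoxide, with 5 of 5 (adjusted p = 0.0393), among them Cybb at 523 ± 257 and Cyba at 5929 ± 1768 (mean ± SD, 5 samples). Cathepsins, mostly lysosomal proteases, had 10 of 13 genes above it (adjusted p = 0.0432) and secondary granule genes 6 of 6 (adjusted p = 0.0233). The cathepsins above it included Ctsg of the neutrophil list and Ctsb, Ctsd and Ctss of other fixed lists. The cathepsin result is thus not separate from those lists. Hox genes, developmental regulators, were above it less often, with 2 of 31 (adjusted p = 2.12e-05), namely Hoxa4 at 481 ± 332 and Hoxa7 at 432 ± 363. Primary granule genes, 4 of 4 (exact adjusted p = 0.0589), late neutrophil genes, 4 of 7 (0.796), Toll-like receptors and adaptors, 3 of 5 (0.796), and integrins together with the integrin-binding protein gene Itgb1bp1, 9 of 20 (1), did not pass. For 4 genes all above the limit, the unadjusted exact p of 0.0393 was the lowest possible, so the primary granule result reflects list size. Both granule lists were drawn from the fixed neutrophil list, with 15 of 16 genes above the limit. They therefore add no separate result.

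The labels do not give the sex of the animals. Signals in samples 1 to 5 were 283, 1051, 14.4, 68.7 and 28.6 for Xist, which is transcribed from the inactive X chromosome, and 19.9, 7.68, 374, 367 and 305 for the Y-linked gene Eif2s3y. Xist thus lay above the array median in samples 1 and 2 alone, and Eif2s3y in samples 3, 4 and 5 alone. The Y-linked genes Kdm5d, with 39.0, 11.5, 14.4, 59.9 and 27.6, and Uty, with 10.2, 50.2, 81.2, 77.4 and 48.2, were below the median on all 5 arrays. Xist and Eif2s3y argue against 1 animal as the source of all 5 samples, while Kdm5d and Uty were too low to tell. Whether sex accounts for other differences between the samples was not tested.

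Shifts of these later lists were tested where at least 3 genes were left, not 5 as for the fixed lists, and adjusted over 45 pairs of list and sample. The primary and secondary granule genes all belong to the fixed neutrophil list. In sample 1 the 4 primary granule genes (Mpo, Elane, Prtn3 and Ctsg) lay 1.38 log2 units above random lists, with 4 of 4 higher (permutation adjusted p = 0.00300), while secondary granule genes lay at -0.70, with 1 of 6 higher (adjusted p = 0.0229). In sample 4 the secondary granule genes were at 0.74 (permutation adjusted p = 0.00300) and the primary ones at -0.33 (0.196). The top 1% of all probe sets lay at -0.64 in sample 1 and 0.48 in sample 4, the directions of the secondary granule genes, and matching by decile does not remove this. In sample 5 both were higher, the primary ones by 0.59 (permutation adjusted p = 0.0225) and the secondary ones by 0.48 (0.0255). The primary ones were lower in sample 2 (-0.84, permutation adjusted p = 0.0146) and sample 3 (-0.72, 0.00300), where the secondary ones did not pass (0.367 and 0.202). NADPH oxidase genes were higher in sample 1 (0.85, permutation adjusted p = 0.0120) and sample 5 (0.67, 0.0146) and lower in sample 2 (-0.57, 0.0450) and sample 3 (-0.77, 0.00900). Relative to random lists, oxidative phosphorylation genes were higher in sample 1 (0.32, permutation adjusted p = 0.00450) and lower in sample 4 (-0.17, 0.0180). Their own median shift in sample 4 was 0.098, with 31 of 52 genes above their 5-sample mean, as in sample 1. The list with integrins was lower in sample 3 (-0.40, permutation adjusted p = 0.0450). Of the 4 Hox genes left, 3 were higher in sample 2 (list shift 0.64, permutation adjusted p = 0.0480). Differences between lists were not tested.

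For the wide spread of neutrophil granule genes, a signal ceiling in sample 1 stays open for the list as a whole. Without sample 1 the permutation adjusted p was 0.294, but the list stayed at the 97.1 percentile of random lists. A ceiling would lower signals, whereas the 4 primary granule genes lay 1.38 log2 units above random lists in sample 1, with 4 of 4 higher. These values argue against a ceiling as the source of the spread of these 4 genes. More mature neutrophils in samples 4 and 5 may contribute, yet the late neutrophil genes had median shifts of 0.29 and 0.35 there, or 0.07 and 0.44 relative to random lists, of which neither passed (permutation adjusted p = 0.811 and 0.150), so this stays open. For the higher signals of primary granule genes in sample 1, unequal 3' bias stays open, since 1 of 3 control transcripts had lower 3' over 5' ratios in samples 1 and 5 than in the others. No biological explanation from the design was tested, because the labels give 1 group.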
